A study of Xenopus laevis with 16 samples.

How the data were processed

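Total RNA from Xenopus laevis hindlimb tissue was amplified with the Affymetrix 2-cycle kit from 1 microgram per array and hybridised to single-colour Affymetrix Xenopus arrays, per the labels' protocols and the series' design text. The series holds 16 arrays in 4 groups of 4, given by the array titles: stage 53 at 1 day, stage 53 at 5 days, stage 57 at 1 day and stage 57 at 5 days after amputation. Titles otherwise carry only a running array code, and replicate numbers used here only name arrays. Each group fills a consecutive block of codes, and all stage 53 codes come before all stage 57 codes. Whether the code follows the order of processing was not given. Any effect of that order could not be separated from stage and day. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No scan date, slide or batch was used here.

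The deposited values are MAS5 signal intensities on a linear scale, per the submitters' processing notes. The MAS5 version and scaling target were not given in the sources used here. In the value table the mean after removal of the outer 2 percent of rows at each end was about 1000 on every array, between 1000.1 and 1000.2, and values ran from 0.6 to 325607.8 with 0 values at or below 0. No detection calls were used, so a low signal here is not separated from background, and folds of dim probe sets are uncertain. The number of arrays limits the precision.

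The table holds 15611 probe sets, of which 120 are Affymetrix controls. Of the other 15491, 9304 carried 1 gene symbol, 195 carried several and 5992 carried none in the platform annotation. Of the probe sets with 1 symbol, 9227 matched a gene of the RefSeq annotation of assembly Xenopus_laevis_v10.1 by Entrez identifier, and 2 symbols were updated. No gene is named from a probe set with several symbols. Symbols end in L or S for the 2 subgenomes of this species, and no coordinates were used. List members were matched by symbol, with 46 matched through a synonym. Matches that joined a list symbol to a gene of another name and function were left out on the names alone.

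Values were transformed to log2 without an offset. Controls were left out, and probe sets whose mean log2 signal lay above the 25th percentile were kept, which left 11618. Group means were fitted to all 16 arrays together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend). There were 5 contrasts: stage 53 minus stage 57 at 1 day and at 5 days, 5 days minus 1 day at each stage, and the difference between the last pair, called the interaction. P-values were adjusted per contrast by the Benjamini-Hochberg method, and a call is an adjusted p below 0.05. All adjusted p-values of genes below are from this limma fit.

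The gene lists, the rule for named genes and the first set of alternatives below were chosen before the data were examined. There were 22 gene lists: skeletal muscle, myogenic regulators, cartilage, bone, cell cycle and DNA replication, limb patterning, FGF signalling, WNT signalling, BMP and TGF-beta signalling, myeloid cells, lymphoid cells and antigen presentation, inflammatory and early injury response, proteases and matrix turnover, fibrillar matrix and fibroblasts, epidermis, erythroid cells, endothelium, nerve and Schwann cells, thyroid hormone response, heat shock and protein folding, mitochondrial respiration, and ribosomal proteins. Each gene was represented by its brightest kept probe set. Lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and the 5 contrasts. No list call held with a correlation estimated from the data, and that adjusted p is given beside each call. The estimate ran from -0.001 for nerve and Schwann cells to 0.512 for ribosomal proteins. The mean of each list per array was also compared between groups with exact two-sided permutation tests, 88 in all, chosen after seeing the data. With 4 arrays against 4 the smallest p they can give is 0.0286, and the smallest after Benjamini-Hochberg adjustment was 0.0932. No list mean therefore passed.

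Named genes follow a fixed rule. For each comparison of groups it takes the 8 largest increases and 8 largest decreases among called genes whose arrays do not overlap between the groups. The higher group's mean had to exceed the median of all probe sets, and the probe set had to carry 1 informative symbol. The interaction takes 5 each way. Up to 4 members of each list described are added by smallest p, with a fixed set of limb, thyroid hormone, matrix and epidermal genes in the stage comparisons. Of that set, fgf10, shh, hoxa13 and klf9 had no kept probe set, and prrx1, sall4, thrb and mmp9 matched no probe set with 1 symbol.

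The alternatives were quantile normalization, centring on array medians, 2 offsets (31.3 and 101.8, the 10th and 25th percentiles of the deposited values), no filter, a filter at the 50th percentile, no intensity trend, array weights, a fit of the 8 arrays compared, a threshold of 0.01, a 2-fold minimum, and each array left out in turn. For lists they were also an estimated correlation, fry, and the mean over a gene's probe sets. After seeing the data, a fit without 3 arrays whose beta-actin 3' to 5' log2 ratio exceeded 4, and a fit with that ratio as a covariate, were added. An estimated correlation was run for the lists on all 16 arrays only.

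The procedure was tested on simulated data made from the measured means, the pooled spread and the spread of each array, with 100 probe sets changed 2-fold and 100 changed 4-fold among 11618 per contrast. Of the 4-fold changes, 66 were called for stage at 1 day, 75 for stage at 5 days, 81 for day at stage 53, 79 for day at stage 57 and 44 for the interaction. Of the 2-fold changes, 19, 14, 21, 13 and 1 were called in that order. For day at stage 57, 20 of the 112 calls in the simulation were of unchanged probe sets. Simulated noise was independent between probe sets. In the measured data the first principal component held 41.1 percent of the variance and correlated at 0.904 with the beta-actin ratio. The shares recovered may therefore differ in these data. Figures were drawn with matplotlib 3.10.9.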

Results

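Gene expression was measured in amputated hindlimbs of tadpoles of Xenopus laevis, the African clawed frog. Limbs had been cut through the mid-zeugopodium, the lower leg segment, at stage 53, which the study describes as competent to regenerate, or at stage 57, described as not competent. Tissue lying 1 mm proximal to the amputation level was taken 1 or 5 days later. Each of the 4 combinations of stage and day has 4 arrays. No unamputated limb was analysed here, so differences are between stages or days and not against an uninjured limb. Values are log2 MAS5 signals.

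Arrays of a group correlated with each other at 0.767 to 0.955 over all probe sets, with a median of 0.923. Of 3 measures of RNA or hybridisation quality, none passed between the stages after adjustment. However, 3 stage 57 arrays lay apart in the first and read highest in all 3. The log2 ratio of the 3' to the 5' beta-actin control probe set was 4.7 and 4.76 in replicates 2 and 3 of stage 57 at 1 day, and 5.72 in replicate 2 of stage 57 at 5 days. On the other 13 arrays it lay between 0.01 and 2.38. By stage it was 2.45 ± 2.29 at stage 57 and 0.47 ± 0.41 at stage 53 (SD, n = 8 each, exact two-sided permutation p = 0.0336, Benjamini-Hochberg p = 0.101 over the 3 measures). The same ratio for GAPDH was 4.92 ± 1.27 and 4.44 ± 0.50 (exact permutation p = 0.352, 0.436 adjusted), and the spiked control bioB read 9.85 ± 0.87 and 9.58 ± 0.30 on the log2 scale (exact permutation p = 0.436, 0.436 adjusted). On the 3 stage 57 arrays, in the order above, the GAPDH ratio was 5.46, 7.33 and 6.17, against 5.22 or less elsewhere. Their bioB readings were 9.99, 11.39 and 10.87, against 9.96 or less elsewhere. Those 3 stage 57 arrays also had the highest signals of the spiked control transcript dap, from 11.52 to 16.01 on the log2 scale. The other arrays read 9.64 or less. Counts below are given for all 16 arrays and without these 3 stage 57 arrays. Their removal leaves 2 arrays of stage 57 at 1 day and 3 at 5 days. A call that ends or appears there may reflect fewer arrays, single arrays or RNA quality, which were not separated.

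**Figure D1:**
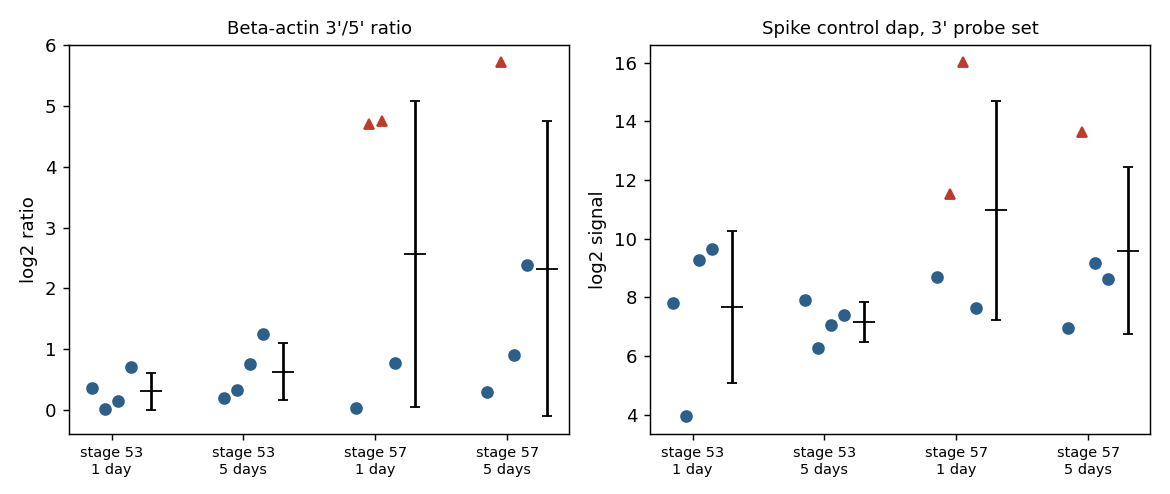
The log2 ratio of 3' to 5' beta-actin probe sets (left) and the log2 signal of the spiked transcript dap (right) per array, by stage and day, with red triangles for the 3 arrays whose actin ratio exceeds 4 and black bars for the group mean and SD (n = 4). The 3 stage 57 arrays lie above the other 13 arrays in both panels.

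The first comparison asks how limbs of the 2 stages differed 1 day after amputation. At stage 53, 23 of 34 measured skeletal muscle genes were lower and 11 did not pass (camera adjusted p = 2.45e-27 for the list, adjusted p = 0.0979 with an estimated correlation). Among the 23, des.1.S, encoding the intermediate filament desmin, was 31.0-fold lower (log2 difference -4.95, SE 0.55, n = 4 per group), and the troponin genes tnnt3.S and tnnc2.S were 11.1-fold and 11.5-fold lower. The gene dio3.L, encoding the deiodinase that inactivates thyroid hormone, was 25.9-fold lower (-4.69, SE 0.66). The gene hand2.S, a transcription factor of posterior limb bud identity, was 10.6-fold higher (3.41, SE 0.44, adjusted p = 0.000374). Complement component c3.L was 8.38-fold higher (3.07, SE 0.36).

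In all, 115 probe sets were higher and 181 lower at stage 53 at 1 day, against 79 and 167 without the 3 stage 57 arrays. Of the 296 calls, 154 were also called without those arrays, and all 285 that could be tested there kept their sign. The 2 fits share most arrays, so such agreement, here and below, was partly fixed in advance. Among called genes within the naming rule's limits on signal, overlap and symbol, the largest increases were pcbd1.L (3.5), hand2.S (3.41), c3.L (3.07), the keratin krt12.2.S (2.69), the proton pump subunit atp6v1b1.L (2.62), plscr2.S (2.5), st3gal2.2.S (2.48) and msi1.S (2.43). Within the same limits the largest decreases were the muscle gene cavin4.S (-5.68), the keratin krt78.6.L (-5.65), klhl41.L (-5.49), des.1.S (-4.95), the keratin krt12.6.S (-4.69), dio3.L (-4.69), ocm4.4.S (-4.58) and mustn1.L (-4.44). The calls of krt12.2.S, plscr2.S and krt12.6.S ended without the 3 arrays, at adjusted p = 0.0699, 0.113 and 0.125, pcbd1.L differed by 1.93, and krt78.6.L and klhl41.L were not tested there because of the filter on low signals. The balance of higher and lower calls depended on single arrays. It was 62 and 115, 22 and 110, or 42 and 120 without replicate 1, 3 or 4 of stage 53 at 1 day, and 45 and 129, 71 and 124, or 312 and 251 without replicate 2, 3 or 4 of stage 57 at 1 day. A fit of the 8 arrays compared gave 26 and 114.

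Of 34 measured skeletal muscle genes, 23 were lower and 0 higher at stage 53 at 1 day, and 28 were lower when adjusted over the list alone. The median log2 difference was -2.6 (camera adjusted p = 2.45e-27, adjusted p = 0.0979 with an estimated correlation). The mean of the list was 7.49 ± 0.40 at stage 53 and 9.88 ± 0.56 at stage 57 (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible, and 0.0932 after Benjamini-Hochberg adjustment over 88 tests). In the fit without the 3 arrays of high actin ratio 22 of 32 measured muscle genes were lower, with a median of -3.07. None of the 5 measured myogenic regulators passed in limma, and their list did not pass (median -0.58, camera adjusted p = 0.158).

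Of 27 fibrillar matrix and fibroblast genes, 6 were lower and 0 higher at stage 53 at 1 day, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 3e-05, adjusted p = 0.269 with an estimated correlation). There were 8 lower without the 3 arrays. Collagen col3a1.S differed by -1.73 (SE 0.32), the protease gene fap.L by -1.77 and collagen col6a1.L by -1.18, of which col6a1.L reached only adjusted p = 0.0508 without the 3 arrays. Of 10 cartilage genes, the matrilins matn2.L (-2.24) and matn1.L (-2.94) were lower, and 4 were lower adjusted over the list alone (median -1.24, camera adjusted p = 0.00452, adjusted p = 0.444 with an estimated correlation). Leaving the 3 arrays out, 2 cartilage genes were lower and the median was -1.02. Another member, matn4.L, differed by -2.45 at adjusted p = 0.0664.

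Of 12 nerve and Schwann cell genes, only ncam1.S was lower (-1.6, SE 0.38), and 5 were lower adjusted over the list alone (camera adjusted p = 0.0176, adjusted p = 0.142 with an estimated correlation). That gene did not pass without the 3 arrays (adjusted p = 0.149), while chrna1.L did (-2.66, adjusted p = 0.0251). The latter encodes an acetylcholine receptor subunit of skeletal muscle, so its call is not specific to nerve. The 77 cell cycle and DNA replication genes shifted lower as a set at stage 53 (median -0.35, camera adjusted p = 0.000133, adjusted p = 0.588 with an estimated correlation). By limma 0 of them passed, and 0 passed adjusted over the list alone, with mcm2.L at -1.22 (adjusted p = 0.0637). The median was -0.4 without the 3 arrays. Compared array by array, the cell cycle list mean did not differ (exact permutation p = 0.429, 0.572 adjusted). The nerve list did not pass without replicate 1 or 4 of stage 57 at 1 day (adjusted p = 0.0536 and 0.0545), nor the cell cycle list without replicate 1 of stage 53 at 1 day (adjusted p = 0.105) or replicate 4 of stage 57 at 1 day (0.0792).

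Of 29 epidermis genes at 1 day, atp6v1b1.L and the keratin krt8.1.S (1.78) were higher and the keratin krt70.S (-2.78) lower at stage 53, with 4 higher and 2 lower adjusted over the list alone. The called probe set of krt12.2.S is not counted here, since a brighter probe set of that gene, which did not pass, stood for it. The list shifted higher (median 0.35, camera adjusted p = 0.0409, adjusted p = 0.584 with an estimated correlation), but not past the threshold without the 3 arrays (adjusted p = 0.0635). It passed under 14 of 29 alternatives (adjusted p = 0.00904 to 0.584), and not without replicate 1 or 4 of stage 53 at 1 day (adjusted p = 0.241 and 0.064), replicate 1, 3 or 4 of stage 53 at 5 days (0.0712, 0.0704 and 0.0711), replicate 3 or 4 of stage 57 at 1 day (0.102 and 0.0977) or replicate 2 or 4 of stage 57 at 5 days (0.0628 and 0.0504). With the 3 arrays left out krt8.1.S and krt70.S were at adjusted p = 0.264 and 0.08. Of 25 inflammatory and early injury genes, c3.L was higher while 3 were lower, among them complement c1s.L (-2.13) and the protease inhibitor a2m.S (-1.99). Adjusted over the list alone 3 were higher and 3 lower. The mean of the inflammatory list gave exact permutation p = 0.229 (0.429 adjusted). The list as a set was higher (median 0.56, camera adjusted p = 0.0482, adjusted p = 0.588 with an estimated correlation), and did not pass without the 3 arrays (adjusted p = 0.247). It passed under 11 of 29 alternatives (adjusted p = 0.0159 to 0.588), and not without replicate 1 of stage 53 at 1 day (adjusted p = 0.145), replicate 1, 3 or 4 of stage 53 at 5 days (0.0502, 0.0916 and 0.0617), replicate 3 or 4 of stage 57 at 1 day (0.245 and 0.108) or replicate 1, 2, 3 or 4 of stage 57 at 5 days (0.0656, 0.0628, 0.0544 and 0.0527).

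Of 42 limb patterning genes, 4 were higher and 0 lower at stage 53 at 1 day, and 5 were higher adjusted over the list alone. The list reached camera adjusted p = 0.0545, passed under 16 of 29 alternatives, and reached 2.48e-08 without the 3 arrays, where 8 of 46 measured genes were higher. The homeobox gene msx1.L was among the 4 (1.62, SE 0.36, adjusted p = 0.0247), at adjusted p = 0.093 without the 3 arrays. Among fixed genes that did not pass at 1 day, msx2.L differed by 1.33, fgf8.L by 0.07, hoxa11.S by 0.19, hoxd13.S by -0.33, col2a1.S by -1.29 and krt12.5.S by 0.25. A second msx2.L probe set read -0.43, and without the 3 arrays hoxd13.S read 0.22 and msx2.L passed at 2.33 (adjusted p = 0.0104). The ribosomal protein list did not pass with all arrays (median -0.32, camera adjusted p = 0.129) and lay in the other direction without the 3 arrays (median 0.25, camera adjusted p = 2.25e-08). The lists of BMP and TGF-beta signalling (camera adjusted p = 0.00278), proteases (0.0384) and thyroid hormone response (0.0384) did not pass with all arrays and passed without the 3 arrays. Of 29 alternatives they passed under 3, 1 and 6. Leaving out replicate 4 of stage 57 at 1 day left 4 lists past the threshold where all arrays gave 7.

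The next comparison asks how the stages differed 5 days after amputation. At stage 53, 13 of 42 measured limb patterning genes were higher and 29 did not pass (camera adjusted p = 1.16e-07 for the list, adjusted p = 0.149 with an estimated correlation). Among the 13, hand2.S was 10.8-fold higher (3.43, SE 0.44, n = 4 per group), sall3.L, a zinc finger gene, 9.56-fold (3.26, SE 0.45) and grem1.L, encoding the BMP antagonist gremlin, 7.48-fold (2.9, SE 0.38). The growth factor gene fgf8.L was 4.47-fold higher (2.16, SE 0.47, adjusted p = 0.00996). Lower at stage 53 were dio3.L, by 90.7-fold (-6.5, SE 0.66), the collagenase gene mmp1.S, by 36.8-fold (-5.2, SE 0.76), and the skeletal muscle actin acta1.S, by 45.1-fold (-5.49, SE 0.81).

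At 5 days 404 probe sets were higher and 452 lower at stage 53, against 961 and 876 without the 3 stage 57 arrays. With arrays centred on their medians, which moved the median difference over all probe sets from 0.102 to 0.002, the split was 297 higher and 575 lower. Of the 856 calls, 834 were also called without the 3 arrays. Without replicate 2, 3 or 4 of stage 53 at 5 days 231 were higher and 314 lower, 179 and 270, or 153 and 255. Without replicate 3 of stage 57 at 5 days the counts were 179 and 253, and without replicate 3 of stage 57 at 1 day 737 and 631. Within the naming rule's limits the largest increases were capn8.3.L (4.99), the proton pump subunit atp6v0a4.L (4.07), the LIM homeobox gene lhx2.L (4.04), cyp1a1.L (3.84), gprc5cl2.S (3.55), hand2.S (3.43), mycn.S (3.38) and sall3.L (3.26). Other kept probe sets disagreed for gprc5cl2.S, reading -0.67 and -0.2, and a second lhx2.L probe set read 0.63 at adjusted p = 0.595. The lhx2.L difference was widened by replicate 3 of stage 57 at 5 days, at 2.56 against 6.1 for the nearest array. It was narrowed by replicate 1 of stage 53 at 5 days, at 8.17 against 9.58. The largest decreases within them were dio3.L (-6.5), krt78.6.L (-6.17), the muscle calcium-binding gene casq1.S (-5.59), acta1.S (-5.49), lgals1.1.S (-5.33), mmp1.S (-5.2), ocm4.4.S (-5.06) and des.1.S (-4.53). Of these krt78.6.L and lgals1.1.S were not tested without the 3 arrays.

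Of 42 limb patterning genes, 13 were higher and 0 lower at stage 53 at 5 days, and 17 were higher adjusted over the list alone. The median was 0.81 (camera adjusted p = 1.16e-07, adjusted p = 0.149 with an estimated correlation), and 22 of 46 measured genes were higher without the 3 arrays. The list mean was 9.01 ± 0.12 at stage 53 and 7.91 ± 0.25 at stage 57 (SD, n = 4 each, exact permutation p = 0.0286, 0.0932 adjusted). The homeobox genes msx1.L (2.28, SE 0.36, adjusted p = 0.0011) and msx2.L (2.53, SE 0.55, adjusted p = 0.00998) were higher, the latter with a second probe set at 0.3. The genes hoxa11.S (0.7), hoxd13.S (0.81), col2a1.S (-1.42) and krt12.5.S (0.54) did not pass. Of these hoxa11.S (1.0, adjusted p = 0.0342) and krt12.5.S (0.58, adjusted p = 0.0417) passed without the 3 arrays.

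Of 10 FGF signalling genes, fgf8.L and the FGF target spry2.L (2.02) were higher and the early response gene egr1.L (-1.81) lower, with 5 higher and 1 lower adjusted over the list alone. The list was higher at camera adjusted p = 0.0477 (adjusted p = 0.225 with an estimated correlation). It passed under 17 of 29 alternatives (adjusted p = 0.0156 to 0.583), and not without replicate 2 of stage 53 at 1 day (adjusted p = 0.0528), replicate 1 or 2 of stage 53 at 5 days (0.0785 and 0.0841), replicate 3 or 4 of stage 57 at 1 day (0.0583 and 0.0545) or replicate 2 or 3 of stage 57 at 5 days (0.0761 and 0.0954). With the 3 arrays left out 5 of 11 measured genes were higher and 1 lower.

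Of 34 skeletal muscle genes, 21 were lower and 0 higher at 5 days, with 25 lower adjusted over the list alone (median -2.15, camera adjusted p = 9.03e-23, adjusted p = 0.0979 with an estimated correlation). The list mean was 7.96 ± 0.30 at stage 53 and 10.21 ± 0.65 at stage 57 (SD, n = 4 each, exact permutation p = 0.0286, 0.0932 adjusted). Of 32 measured without the 3 arrays of high actin ratio, 22 were lower. The troponin genes tnnt3.S (-3.42) and tnni2.S (-3.19) were among them.

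Of 27 fibrillar matrix and fibroblast genes, 11 were lower and 1 higher at 5 days, with 15 and 1 adjusted over the list alone (camera adjusted p = 1.52e-08, adjusted p = 0.179 with an estimated correlation). Tenascin tnc.L differed by -2.75, collagen col3a1.S by -2.31 and the secreted matrix-associated gene ccn2.L by -3.22. There were 18 lower and 1 higher without the 3 arrays. Of 10 cartilage genes, matn2.L (-2.65) and matn4.L (-2.65) were lower, and 6 were lower adjusted over the list alone (camera adjusted p = 8.91e-05, adjusted p = 0.25 with an estimated correlation). There were 4 lower without the 3 arrays. The cartilage list mean gave exact permutation p = 0.0571 (0.162 adjusted). Its arrays overlapped, with replicate 1 of stage 57 at 8.97 and replicate 2 of stage 53 at 9.41.

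Of 18 genes of proteases and matrix turnover, 6 were lower and 1 higher at 5 days, in the same numbers adjusted over the list alone (camera adjusted p = 0.000488, adjusted p = 0.0979 with an estimated correlation). They included mmp1.S, mmp28.L (-1.63) and the plasminogen activator plat.L (-1.82). Leaving the 3 arrays out gave 9 lower and 1 higher. Of 20 thyroid hormone response genes, 5 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.000168, adjusted p = 0.0979 with an estimated correlation). These included dio3.L, mmp1.S and crhbp.S (-1.86), which encodes a binding protein of corticotropin-releasing hormone. There were 9 lower without the 3 arrays. The list shares 8 of its members with other lists.

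Of 25 inflammatory and early injury genes, 5 were lower and 1 higher at 5 days, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.00915, adjusted p = 0.453 with an estimated correlation). They included a2m.S (-3.13), c1s.L (-3.0) and socs3.L (-1.9), which encodes a suppressor of cytokine signalling. There were 9 lower and 1 higher without the 3 arrays. Of 30 heat shock and protein folding genes, 4 were lower, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000133, adjusted p = 0.213 with an estimated correlation). The endoplasmic reticulum genes hspa5.L (-2.63), pdia6.L (-2.39) and hsp90b1.L (-1.83) were among the 4. Again 9 were lower and 1 higher without the 3 arrays.

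The other 13 lists did not pass at 5 days. The nerve and Schwann cell list was at camera adjusted p = 0.0677, endothelium at 0.075, epidermis at 0.0967, myeloid cells at 0.106, BMP and TGF-beta signalling at 0.116, mitochondrial respiration at 0.116, erythroid cells at 0.171, myogenic regulators at 0.275, bone at 0.317, WNT signalling at 0.393, cell cycle at 0.401, ribosomal proteins at 0.797, and lymphoid cells and antigen presentation at 0.984, with a median of 0.16 although the test pointed lower. When the 3 arrays were left out, epidermis (adjusted p = 0.0192), erythroid cells (0.0384), mitochondrial respiration (0.0384), myeloid cells (0.0381) and ribosomal proteins (4.26e-05) passed as well.

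**Figure D2:**
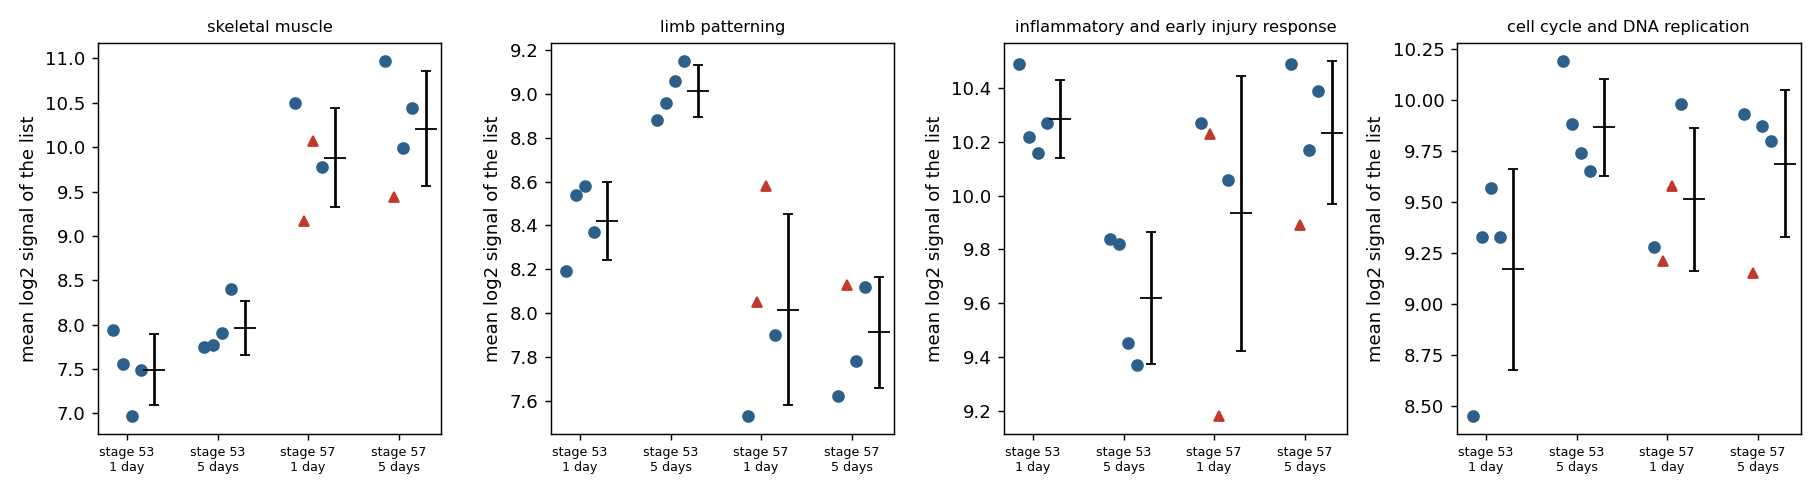
Mean log2 signal of 4 gene lists on each array, by stage and day, with red triangles for the 3 arrays of high actin ratio and black bars for the group mean and SD (n = 4). The skeletal muscle mean lies between 6.97 and 8.4 on the stage 53 arrays and between 9.17 and 10.97 on the stage 57 arrays.

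Stage differences on the 2 days were compared across all 11618 probe sets, which come from separate arrays on each day. They correlated at Pearson r = 0.708 (jackknife SE over arrays 0.163) and Spearman rho = 0.643 across probe sets, which are not independent replicates. Of the calls, 76 were higher at stage 53 on both days, where independent lists would share 4, and 134 were lower on both, where they would share 7.04. Without the 3 arrays r was 0.69 and rho 0.577, with 66 higher and 154 lower on both days, where independent lists would share 6.53 and 12.6. No probe set was called in opposite directions in either fit. The genes des.1.S, dio3.L, hand2.S and ocm4.4.S were among those called the same way on both days.

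**Figure D3:**
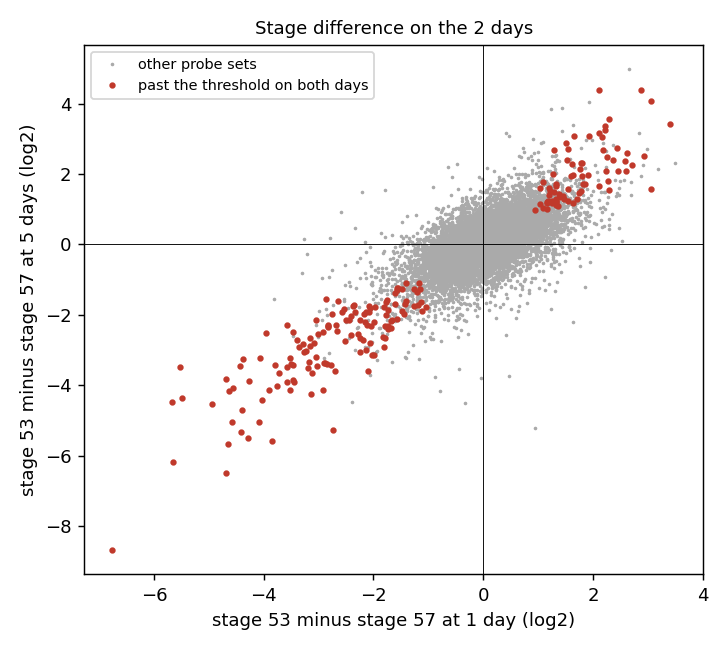
Stage 53 minus stage 57 log2 difference of each of 11618 probe sets at 1 day (horizontal) and 5 days (vertical), with probe sets past the threshold on both days in red. The red points lie in the lower left and upper right quadrants, and r is 0.708 across probe sets.

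The day comparison at stage 53 asks what changed between 1 and 5 days in the limbs described as competent. The collagenase gene mmp1.S fell 38.4-fold (-5.26, SE 0.76, n = 4 per group), the keratin krt17.S 20.8-fold (-4.38, SE 0.43, adjusted p = 0.000167) and sln35-A 19.3-fold (-4.27, SE 0.77). The gene dynll1.S, encoding a dynein light chain, rose 10.8-fold (3.44, SE 0.47) and the phospholipid transfer gene pltp.S rose 5.34-fold (2.42, SE 0.4). Another dynll1.S probe set read -0.68 at adjusted p = 0.397, and one for dynll1.L read 0.27. The stress gene gadd45g.S (-2.53), aif1l.L (-2.37) and socs3.L (-2.06) also fell.

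Only 4 probe sets rose and 10 fell at stage 53, with 1111 at an unadjusted p below 0.05 where 581 would be expected by chance. In the fit without the 3 stage 57 arrays, which enter this comparison through the shared estimate of spread and the filter on low signals, 153 rose and 218 fell, all 14 of the first calls among them. With arrays centred on their medians 4 rose and 21 fell. Leaving out replicate 1 or 4 of stage 53 at 1 day gave 6 calls each, replicate 3 or 4 of stage 53 at 5 days 8 or 5, replicate 3 or 4 of stage 57 at 1 day 92 or 30, and replicate 2 of stage 57 at 5 days 41.

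The 77 cell cycle and DNA replication genes were higher as a set at 5 days (median 0.7, camera adjusted p = 2.12e-16, adjusted p = 0.215 with an estimated correlation). By limma 0 passed over all probe sets, and 9 were higher adjusted over the list alone, as were 9 over all probe sets without the 3 arrays. The replication genes mcm5.L and cdc6.L stood at 1.07 and 1.03 (adjusted p = 0.11 and 0.137, and 0.0305 and 0.0412 without the 3 arrays). Limb patterning genes were also higher as a set (median 0.67, camera adjusted p = 1.2e-05, adjusted p = 0.209 with an estimated correlation), with 0 of 42 passing over all probe sets or over the list alone and 4 without the 3 arrays. The zinc finger gene sall1.L stood at 2.34 (adjusted p = 0.141). FGF signalling genes were higher (camera adjusted p = 0.0252, adjusted p = 0.207 with an estimated correlation), with 0 of 10 passing, 4 higher and 1 lower adjusted over the list alone, and 3 higher without the 3 arrays. With all arrays fgf8.L stood at 1.56 and spry2.L at 1.41. The FGF list did not pass without replicate 2 of stage 53 at 1 day (adjusted p = 0.0688) or replicate 1 or 2 of stage 53 at 5 days (0.0633 and 0.0664).

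Inflammatory and early injury genes were lower as a set at 5 days (median -0.54, camera adjusted p = 4.77e-08, adjusted p = 0.142 with an estimated correlation). Only socs3.L fell over all probe sets, 7 were lower adjusted over the list alone, and 4 fell without the 3 arrays. The transcription factor genes jun.L and cebpb.L stood at -1.53 and -1.65. Myeloid genes (median -0.56, camera adjusted p = 7.35e-05, adjusted p = 0.207 with an estimated correlation) had 0 of 17 passing and 3 lower adjusted over the list alone, with csf2rb.S at -1.88 (adjusted p = 0.0597). In the fit without the 3 arrays 4 myeloid genes fell. Heat shock and protein folding genes (median -0.44, camera adjusted p = 1.81e-06, adjusted p = 0.149 with an estimated correlation) had 0 of 30 passing, 6 lower and 1 higher adjusted over the list alone, and 7 that fell without the 3 arrays. Proteases and matrix turnover (camera adjusted p = 0.00528, adjusted p = 0.162 with an estimated correlation) had mmp1.S as its 1 call and 3 lower adjusted over the list alone, with mmp11.L at -2.17 (adjusted p = 0.0973), and 4 fell without the 3 arrays. Thyroid hormone response genes (camera adjusted p = 0.00426, adjusted p = 0.0979 with an estimated correlation) had the same call and 3 lower adjusted over the list alone, and 2 fell without the 3 arrays.

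Erythroid genes (median -0.67, camera adjusted p = 0.000206, adjusted p = 0.213 with an estimated correlation) and epidermis genes (median -0.32, camera adjusted p = 0.00281, adjusted p = 0.374 with an estimated correlation) were lower as sets at 5 days. Skeletal muscle genes (median 0.45, camera adjusted p = 0.0176, adjusted p = 0.641 with an estimated correlation) and lymphoid genes (median 0.83, camera adjusted p = 0.0407, adjusted p = 0.463 with an estimated correlation) were higher. In these 4 lists 0 members passed over all probe sets or adjusted over the list alone. Their means gave exact permutation p = 0.0286 for erythroid, 0.2 for epidermis, 0.114 for muscle and 0.171 for lymphoid genes, before adjustment. With the 3 arrays left out 1 epidermis gene and 1 muscle gene fell and the lymphoid list was at adjusted p = 0.0635. The muscle list did not pass without replicate 3 of stage 53 at 1 day (adjusted p = 0.292) or replicate 4 of stage 53 at 5 days (0.105). The lymphoid list passed under 19 of 29 alternatives (adjusted p = 0.000591 to 0.463), and not without replicate 3 or 4 of stage 53 at 1 day (adjusted p = 0.228 and 0.158), replicate 1 or 2 of stage 53 at 5 days (0.0993 and 0.107) or replicate 3 or 4 of stage 57 at 1 day (0.0516 and 0.0508). The muscle members myl3.L and ckm.L stood at 1.99 and -1.06, in opposite directions.

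The day comparison at stage 57 asks the same of limbs described as not competent. By limma 0 probe sets passed, with 237 at an unadjusted p below 0.05 where 581 would be expected by chance, and 0 passed with 415 at an unadjusted p below 0.05 without the 3 arrays. Array weights, quantile normalization and the fit of the 8 arrays alone also gave 0, and leaving out replicate 2 of stage 57 at 5 days gave 1. Erythroid genes were lower as a set at 5 days (median -0.54, camera adjusted p = 4.77e-08, adjusted p = 0.0979 with an estimated correlation), with the alpha globin gene hba2.L at -1.9 (SE 0.71, n = 4 per group) and the anion exchanger slc4a1.L at -2.58 (SE 0.86). Fibrillar matrix genes (median 0.41, camera adjusted p = 7.35e-05, adjusted p = 0.313 with an estimated correlation) and cartilage genes (median 0.74, camera adjusted p = 0.00172, adjusted p = 0.385 with an estimated correlation) were higher as sets, with tagln.L at 1.33 and the cartilage regulator sox9.S at 1.11. The cartilage list did not pass without replicate 4 of stage 57 at 1 day (adjusted p = 0.0527) or replicate 4 of stage 57 at 5 days (0.311).

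At stage 57 epidermis genes (median -0.28, camera adjusted p = 6.34e-05, adjusted p = 0.215 with an estimated correlation), heat shock and protein folding genes (adjusted p = 0.0297, adjusted p = 0.503 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.0117, adjusted p = 0.765 with an estimated correlation) were lower as sets. Skeletal muscle (adjusted p = 0.0103, adjusted p = 0.602 with an estimated correlation), inflammatory (adjusted p = 0.0198, adjusted p = 0.515 with an estimated correlation), protease (adjusted p = 0.027, adjusted p = 0.215 with an estimated correlation) and cell cycle genes (adjusted p = 0.0306, adjusted p = 0.777 with an estimated correlation) were higher. In each of these lists 0 members passed, and 0 passed adjusted over the list alone. Means of the lists at stage 57 gave exact permutation p = 0.0857 for erythroid, 0.171 for epidermis, 0.257 for protease and 0.286 for fibrillar matrix genes. For heat shock and cartilage p was 0.343, for inflammatory 0.4, for muscle 0.457, for cell cycle 0.514 and for ribosomal genes 0.714, before adjustment. The ribosomal and inflammatory lists were at adjusted p = 0.0661 and 0.247 without the 3 arrays, while BMP and TGF-beta signalling (0.046), bone (0.0381) and thyroid hormone response (0.0411) passed only there. The ribosomal median was -0.19 with all arrays and 0.07 without the 3 arrays, and replicate 2 of stage 57 at 5 days had a ribosomal mean of 15.35 against 14.42 for the nearest array of its group. The ribosomal list turned to higher without replicate 3 of stage 57 at 1 day (adjusted p = 0.0116) and did not pass without replicate 1, 3 or 4 of stage 57 at 5 days (adjusted p = 0.147, 0.35 and 0.2). Heat shock genes did not pass without replicate 1 or 2 of stage 57 at 1 day (adjusted p = 0.414 and 0.147) or replicate 2 or 4 of stage 57 at 5 days (0.0766 and 0.256), nor muscle genes without replicate 2 or 4 of stage 57 at 1 day (adjusted p = 0.729 and 0.133) or replicate 1 of stage 57 at 5 days (0.998). Inflammatory genes did not pass without replicate 3 or 4 of stage 57 at 1 day (adjusted p = 0.932 and 0.0889) or replicate 1 of stage 57 at 5 days (0.195), the first of these with the test pointing lower. Protease genes did not pass without replicate 3 of stage 57 at 1 day (adjusted p = 0.258) or replicate 1 or 3 of stage 57 at 5 days (0.111 and 0.0544), nor cell cycle genes without replicate 1 or 2 of stage 57 at 1 day (adjusted p = 0.584 and 0.702) or replicate 1 or 3 of stage 57 at 5 days (0.513 and 0.23). Leaving out replicate 1 of stage 57 at 5 days left 5 lists past the threshold where all arrays gave 10.

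The interaction asks whether the change from 1 to 5 days differed between the stages. There 3 genes passed, all with a lower change at stage 53: the keratin krt17.S (log2 difference of the changes -4.18, SE 0.61, n = 4 per group, adjusted p = 0.0363), the matrix metalloproteinase gene mmp13l.L (-3.77, SE 0.61, adjusted p = 0.0483) and socs3.L (-2.54, SE 0.42, adjusted p = 0.0483). Of all probe sets, 461 were at an unadjusted p below 0.05 where 581 would be expected by chance. When the 3 arrays were left out 0 passed by limma, with 769 at an unadjusted p below 0.05, and krt17.S, mmp13l.L and socs3.L were at adjusted p = 0.0858, 0.0858 and 0.11. Leaving out replicate 1 of stage 53 or replicate 4 of stage 57 at 5 days gave 1 call, leaving out replicate 2 of either stage at 5 days gave 2, and leaving out any other array gave 0. The collagenase mmp1.S stood at -6.14 (SE 1.07, adjusted p = 0.0741).

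Inflammatory and early injury genes had a lower change at stage 53 as a set (median -1.09, camera adjusted p = 7.44e-11, adjusted p = 0.0979 with an estimated correlation), with socs3.L as the 1 call and 2 lower adjusted over the list alone. Proteases (median -0.52, camera adjusted p = 5.67e-05, adjusted p = 0.0979 with an estimated correlation), myeloid genes (median -0.64, camera adjusted p = 7.32e-05, adjusted p = 0.207 with an estimated correlation), heat shock genes (median -0.46, camera adjusted p = 0.00528, adjusted p = 0.373 with an estimated correlation), fibrillar matrix genes (median -0.38, camera adjusted p = 0.0067, adjusted p = 0.528 with an estimated correlation) and thyroid hormone response genes (median -0.13, camera adjusted p = 0.0103, adjusted p = 0.135 with an estimated correlation) were also lower. Cell cycle genes (median 0.47, camera adjusted p = 1.56e-08, adjusted p = 0.432 with an estimated correlation), limb patterning genes (median 0.67, camera adjusted p = 1.14e-06, adjusted p = 0.179 with an estimated correlation) and ribosomal genes (median 0.28, camera adjusted p = 0.0297, adjusted p = 0.79 with an estimated correlation) had a higher change. The fibrillar matrix list did not pass without replicate 2 of stage 57 at 1 day (adjusted p = 0.0646) or replicate 3 or 4 of stage 57 at 5 days (0.0776 and 0.0504), the heat shock list without replicate 4 of stage 57 at 1 day (adjusted p = 0.102), or the thyroid hormone list without replicate 4 of stage 57 at 1 day (adjusted p = 0.0704). The ribosomal list passed under 14 of 29 alternatives (adjusted p = 8.28e-06 to 0.917), and not without replicate 1 or 4 of stage 53 at 1 day (adjusted p = 0.154 and 0.0609), replicate 3 or 4 of stage 53 at 5 days (0.0543 and 0.205), replicate 2 or 3 of stage 57 at 1 day (0.0803 and 0.394) or replicate 1, 3 or 4 of stage 57 at 5 days (0.155, 0.258 and 0.205). Adjusted over the list alone, 3 proteases, 3 thyroid hormone response genes and 2 fibrillar matrix genes passed and 0 in the other lists. The ribosomal list was at adjusted p = 0.917 without the 3 arrays, and the cell cycle and limb patterning lists at 3.56e-07 and 0.01, while cartilage (0.0305), erythroid cells (0.0384) and FGF signalling (0.00346) passed there but not with all arrays. Of 29 alternatives they passed under 5, 1 and 12.

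Changes from 1 to 5 days correlated between the stages at Pearson r = 0.188 (jackknife SE over arrays 0.201) and Spearman rho = 0.186 across the 11618 probe sets, which are not independent replicates. Leaving out replicate 1, 2 or 3 of stage 57 at 1 day gave r = 0.082, 0.076 or 0.308, and fitting without the filter on low signals gave 0.074. The correlation was 0.248 without the 3 arrays. Of the 14 probe sets called at stage 53, 9 had a difference of the same sign at stage 57, where 0 passed by limma.

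**Figure D4:**
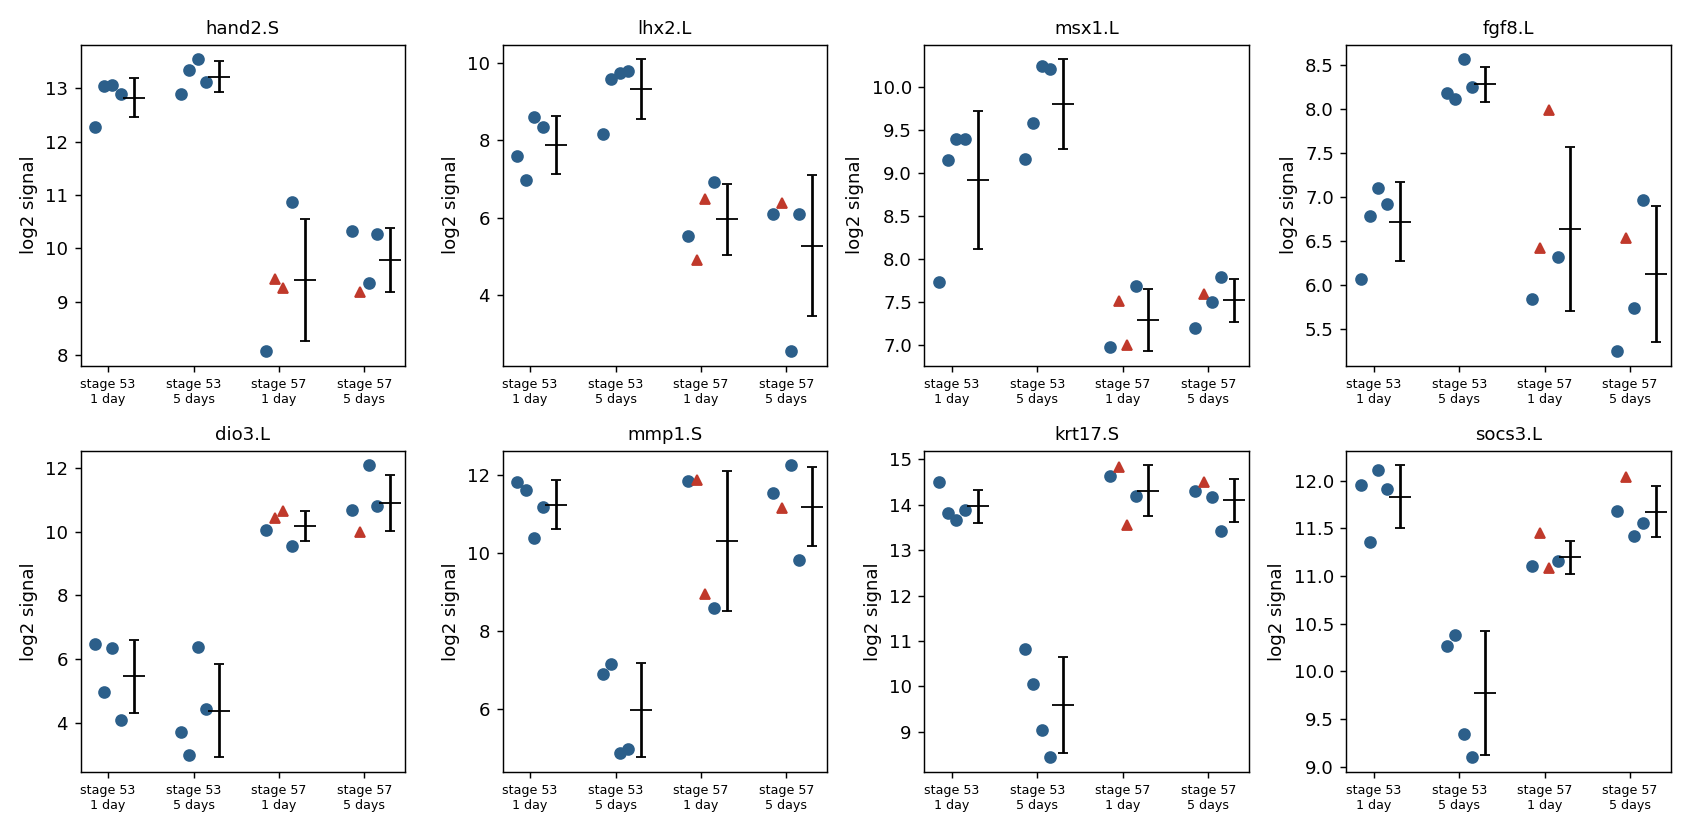
Log2 signal of 8 named genes on each array, by stage and day, with red triangles for the 3 arrays of high actin ratio and black bars for the group mean and SD (n = 4). The genes hand2.S, msx1.L and fgf8.L are higher at stage 53 at 5 days, and krt17.S and socs3.L are lowest in that group.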

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

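Of the tests below, those on the spiked controls, the interaction on residuals, the muscle means of single arrays, the variance of the day effects, the muscle list without the 3 arrays, the share of muscle genes that were lower, and the place of the 3 arrays in the splits were chosen only after the result was seen.

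Within each group of 4 arrays, the gap between the most extreme array and its nearest neighbour was divided by the group's range and compared with Dixon's critical value for 4 samples. Chance gives about 1 such array in 20 groups, and 29 were found in 540 groups where 27 would be expected. Replicate 2 of stage 57 at 5 days, one of the 3 arrays of high actin ratio, stood apart in its correlation with its group (ratio 0.869), in the means of the ribosomal (0.928) and cell cycle (0.841) lists, and in pcbd1.L (0.944), gadd45g.S (0.871), hoxd13.S (0.833), mmp11.L (0.93) and tagln.L (0.919). At stage 57 at 5 days other arrays stood apart in the heat shock list (0.888), c3.L (0.846), lhx2.L (0.926), chrna1.L (0.835) and hhip.L (0.84).

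At stage 57 at 1 day the ratio was exceeded for casq1.S (0.876) and acta1.S (0.847) in replicate 1, for matn1.L (0.844) and hspa5.L (0.895) in replicate 2, and for foxi1.L (0.83) in replicate 3. Replicate 1 of stage 53 at 1 day stood apart in the epidermis list (0.855), msx1.L (0.852), mcm5.L (0.957) and ncaph.L (0.945), and replicate 2 in msx2.L (0.892). At stage 53 at 5 days the arrays concerned were replicate 1 for the BMP and TGF-beta list (0.882), atp6v1b1.L (0.837) and lhx2.L (0.868), replicate 2 for the array median (0.857), and replicate 3 for aif1l.L (0.965) and matn4.L (0.858).

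The change from 1 to 5 days differed between the stages for krt17.S (adjusted p = 0.0363), mmp13l.L (0.0483) and socs3.L (0.0483). By camera it also differed for the lists of inflammatory and early injury response (7.44e-11), cell cycle (1.56e-08), limb patterning (1.14e-06), proteases (5.67e-05), myeloid cells (7.32e-05), heat shock (0.00528), fibrillar matrix (0.0067), thyroid hormone response (0.0103) and ribosomal proteins (0.0297). None of these lists passed with an estimated correlation.

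Other splits of the same arrays were fitted the same way. For stage at 1 day, stage at 5 days and day at stage 53, 1 of 35 splits, the real one, called as many probe sets (296, 856 and 14, against 0 for the highest other). This is the smallest share that 35 splits can give, and it was not corrected over the comparisons. It argues against a random division of these arrays. Chance between animals cannot be excluded, since the replicates may be technical. For day at stage 57 all 35 splits called at least the real 0, and the highest called 2904. Of the 5 splits with the 3 arrays of high actin ratio on one side, 4 called 1109 to 2904 and 1 called 0, while the other 30 called 0, which points to a structure of the samples. For the interaction the stage labels were redrawn within each day on the residuals of stage plus day, and 3 of 100 draws gave the real 3 calls or more, with a highest other of 156. That draw points to a structure of the samples. At an unadjusted p below 0.05 there were 461 probe sets for the interaction, where 581 would be expected by chance. Without the 3 arrays of high actin ratio 0 passed by limma, with 769 at an unadjusted p below 0.05, so these draws are not taken to exclude chance. The agreement of the stage effects between days (0.708) was reached by 1 of 100 draws, the real one, with a highest other of 0.658. This argues against a random assignment of stage to these arrays, with the same limit on chance between animals.

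For counts of gene lists, adjusted within each comparison, chance cannot be excluded. As many lists passed in 19 of 35 splits for stage at 1 day (5 lists, highest other 11), 8 of 35 for stage at 5 days (9 and 12), 2 of 35 for day at stage 53 (12 and 12), 3 of 35 for day at stage 57 (10 and 11) and 11 of 100 draws for the interaction (9 and 12).

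Replicates 2 and 3 of stage 57 at 1 day and replicate 2 of stage 57 at 5 days stood apart from the other 13 arrays. Tissue of stage 53 under a stage 57 label is argued against, since the lowest of the 3 muscle list means (9.17) lay 0.78 above the highest of stage 53 (8.4). Scarce or degraded RNA may account for the pattern, as the 3 arrays held the highest signals of all 4 spiked polyadenylated controls. No biological explanation was tested, and differences of stage 57 tissue or between single limbs or animals stay open.

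The skeletal muscle list was lower at stage 53 on both days. The 3 arrays of high actin ratio are argued against as the whole cause, since the medians without them were -3.07 and -2.49, and so is the scaling between arrays, since the highest median under quantile normalization or centring was -2.19. A smaller share of muscle in the stage 53 tissue and a lower expression within muscle cannot be told apart, because both lower most of the list. The share of muscle genes that were lower was 0.882 at 1 day and 0.941 at 5 days.

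More probe sets changed from 1 to 5 days at stage 53 than at stage 57. Fewer usable arrays at stage 57 cannot be excluded: with stage 53 reduced to the same array numbers and the 3 arrays left out, 24 subsets gave a median of 49 calls, from 1 to 544, against 371 with all 8 stage 53 arrays. In the same subsets stage 57 had 0 calls in 20 and 1 or 2 in the other 4, fewer than stage 53 in all 24, but the low end of the stage 53 counts keeps the explanation open. A smaller change over time at stage 57 may also account for it, as the variance of the day effects beyond their squared errors was 0.092 times that at stage 53 (0.052 to 0.213 over the subsets). The subsets share the same 5 stage 57 arrays.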

How the results depend on the processing

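The fit without the 3 arrays of high actin ratio and the fit with that ratio as a covariate were chosen only after the data were seen. No paired analysis was possible because the titles carry only a running array code.

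Correlations of effects kept their sign under every alternative run, from 0.564 to 0.738 between days and from 0.076 to 0.308 between stages when single arrays were left out. Counts of probe sets moved by over 1.5 times as follows. For stage at 1 day, where all arrays gave 296, the filter at the median gave 135, the fit of 8 arrays 140 and a threshold of 0.01 gave 104, with 132 to 563 when single arrays were left out. For stage at 5 days, with 856, array weights gave 2670, the threshold of 0.01 gave 295, the fit without the 3 arrays 1837 and the covariate 1300, with 408 to 1368 when single arrays were left out. For day at stage 53, with 14, centring gave 25, the smaller offset 22, array weights 828, the fit of 8 arrays 286, the threshold of 0.01 gave 5, the fit without the 3 arrays 371 and the covariate 189, with 5 to 92 when single arrays were left out. Day at stage 57 gave 0 under all alternatives except 1 when replicate 2 at 5 days was left out, a range of 0 to 1. For the interaction, with 3, both offsets, no filter and the filter at the median each gave 1, array weights 11, the threshold of 0.01 and the fit without the 3 arrays 0, and the covariate 6, with 0 to 2 when single arrays were left out. A stricter threshold calls fewer by construction. For day at stage 53, the fit of 8 arrays and the fit without the 3 arrays change no stage 53 mean. They act there only through the estimate of spread and the filter on low signals. For the other settings the cause was not tested.

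Counts of gene lists fell to 0 in all 5 comparisons with an estimated correlation. Against the preset 0.01, it was 0.311 for muscle, 0.364 for cell cycle, 0.465 for cartilage, 0.249 for fibrillar matrix and 0.512 for ribosomal genes. For nerve and thyroid hormone response genes it was -0.001 and 0.008, not above the preset, and their calls ended too. With fry they were 3 for stage at 1 day, 1 for day at stage 53, 0 for day at stage 57 and 1 for the interaction. For stage at 1 day, with 7, the filter at the median gave 4 and the covariate 11, and for stage at 5 days, with 9, the fit without the 3 arrays gave 14. Leaving out single arrays gave 4 to 10 lists for stage at 1 day and 5 to 10 for day at stage 57. For settings other than the estimated correlation the cause was not tested.

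Signs reversed for these named genes, and the cause was not tested. Other probe sets read -0.68 for dynll1.S (day at stage 53), 0.15 for espl1.S and -0.11 for tpm2.S (day at stage 57), -0.67 and -0.2 for gprc5cl2.S (stage at 5 days) and -0.43 for msx2.L (stage at 1 day). Besides these 6 reversals, 12 readings of other probe sets lost the call, 1 gained one and 55 stayed on their side. Not all of the 12 are named above. Without the 3 arrays espl1.S read 0.06 and hoxd13.S at 1 day 0.22, and 0.13 with the covariate. With single arrays left out, values at 1 day reversed to -0.05, -0.19 and -0.03 for fgf8.L (range -0.19 to 0.52), -0.18 for hoxa11.S (range -0.18 to 0.81) and 0.07 for hoxd13.S (range -0.75 to 0.07). Over the genes named in the comparisons and single arrays left out, 146 values lost their call, 25 gained one, 5 reversed and 2199 stayed on their side. Leaving out an array outside a comparison cannot change its log2 difference, and a value not called with all arrays cannot lose a call. Part of the 2199 was therefore fixed in advance. The single list members at 5 days given under other observations are not in this tally. Dim probe sets are limited by background, which no detection call separates here.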

Other observations

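The tests on the proton pump below were chosen only after the result was seen.

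Single members of lists that did not pass also differed between the stages at 5 days. Among WNT signalling genes, wnt11.S (log2 difference -1.64, SE 0.43, n = 4 per group, adjusted p = 0.0296) and wif1.S, encoding a secreted WNT inhibitor (-1.84), were lower at stage 53, and the receptor genes fzd10.S (1.03) and fzd7.L (1.05) were higher. Of the BMP and TGF-beta signalling genes, smad6.L, encoding an inhibitory SMAD (1.13), and the activin receptor acvr2b.S (1.59) were higher and follistatin fst.L (-1.02) lower. The neural crest and Schwann cell regulator sox10.L (-1.88) and the neuronal tubulin tubb3.L (-1.73) were lower, as was the transcription factor ets1.L (-1.77). The membrane skeleton gene epb41.L was higher (2.41, SE 0.32, adjusted p = 0.000282), although its other kept probe sets read 0.87 and 0.38 and did not pass.

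Of 16 measured subunits of the vacuolar proton pump, looked at together only after some of their values were seen, 4 were higher and 1, atp6v1g1.S, was lower at stage 53 at 5 days (-0.87, adjusted p = 0.0348). Then atp6v0a4.L differed by 4.07, atp6v1al.L by 2.69, atp6v1b1.L by 2.59 and atp6v0d2.L by 1.25 (adjusted p = 0.0153), and foxi1.L, a regulator of ion-transporting epidermal cells, by 3.38 (adjusted p = 0.00113). At 1 day the values were 3.06, 2.18 and 2.62 for the first 3, which passed, and 1.01 for atp6v0d2.L and 1.64 for foxi1.L, which did not (adjusted p = 0.0796 and 0.134). Without the 3 arrays of high actin ratio foxi1.L passed at 1 day too (2.12, adjusted p = 0.0437), while atp6v0a4.L read 2.8, atp6v1al.L 1.75, atp6v1b1.L 1.76 and atp6v0d2.L 0.44 (adjusted p = 0.48). The genes atp6v1al.L and atp6v0d2.L were chosen after their values were seen. At 5 days the stage 57 means of atp6v0a4.L, foxi1.L and atp6v1b1.L were 4.53, 4.64 and 6.16. These lay below the 25th percentile of each array of that group (6.46 to 6.99), so the sizes of their differences are uncertain. Those of atp6v1al.L and atp6v0d2.L were 8.19 and 9.26. A rise of all subunits alike is argued against at 5 days, since none of the other 12 exceeded 0.54. Their median was -0.2, from -1.16 to 0.54, and -0.25 without the 3 arrays. The 12 are what remained after the 4 noticed for high values were set aside, which lowers their median. At 1 day their median was 0.43, from -0.71 to 1.08, which decides nothing. Without the 3 arrays it was 0.16, from -0.16 to 0.7, with the same 4 set aside. In that fit the range argues only against a rise of all subunits alike at 1 day. A higher share of ion-transporting epidermal cells at stage 53 may be a candidate explanation, which was not tested.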
